A study of Mus musculus with 4 samples.

How the data were processed

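RNA was measured in 4 hippocampus samples of C57BL/6 mice, 2 from the group labelled control and 2 from the group labelled ATO at 5000 ppb. Per the labels' protocols, total RNA was purified with a kit and libraries were made from messenger RNA with the Illumina TruSeq RNA kit. Per the submitters' processing notes the authors used FastQC 0.10.1, cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1, R 4.1.0, limma 3.47.15 and the mouse build GRCm38; the role of each tool and its settings are not given in the sources used here. Whether reads were counted by strand is not given either, so genes that overlap on opposite strands, near-identical gene copies and pseudogenes can share or exchange reads. Nothing in the labels says that the replicates came from separate litters or animals, so p-values measure the spread between these samples.

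The authors deposited 1 table with 15713 genes. Per the file headers it holds, for each library, the count of reads per gene and the FPKM value. It also holds, per the file headers, the authors' log2 fold change of ATO over control, the authors' p-value and adjusted p-value, and a mark for differential expression. The deposited counts were whole numbers with a different total in each library, and each gene had over 1 CPM in at least 2 libraries, so genes below that level are not analysed here. Between libraries, the ratio of count to deposited FPKM was constant across genes; these FPKM values were not used further. The authors' adjusted p-value equalled a Benjamini-Hochberg adjustment of their p-value over the table, and their mark matched an adjusted p under 0.05 with an absolute log2 fold change over 1 in every row (0 mismatches). Values from the authors' deposited table are named as such; all others were computed from the deposited counts.

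Gene positions came from the GENCODE vM21 annotation of GRCm38, in which 99.9% of the identifiers were found (15703 genes). Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (0 genes removed), TMM factors (0.994 to 1.01), and the quasi-likelihood test of ATO against control with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have passed, risen or fallen. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F. Normalised CPM are counts divided by the TMM-scaled library size. The common dispersion was 0.00513, a biological coefficient of variation of 7.16%. Intervals of ratios at low counts are exact binomial 95% intervals and, like the floor of 3 counts, which is 0.174 to 0.202 CPM in a single library, cover counting error only.

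Before the data were examined, 38 gene lists (pathways, cell types and neighbouring brain regions) and the rule for named genes were fixed. The lists hold 787 genes, of which 728 were tested. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 38 lists; 14 passed, 10 up and 4 down. With an estimated correlation 0 of the 38 lists passed, 3 had an unadjusted p under 0.05, and the smallest adjusted p was 0.552. This setting has little power, as 2 libraries per group leave few degrees of freedom to estimate the correlation. Even the choroid plexus list, of which all 20 members rose, reached only an unadjusted p of 0.0351 there. A list that did not pass there is thus not shown to be unchanged. Conversely, the preset correlation of 0.01 takes the members of a list as nearly independent. Where members move together between libraries, its p-values are too small, and a pass can overstate the evidence. Fry's directional test, which asks whether a list's genes move on balance one way and does not compare them with other genes, gave 0 lists at an adjusted p under 0.05 and 11 at an unadjusted p under 0.05. Median, mean and test direction differed in sign for 3 lists, the NRF2 targets, the chromatin enzymes and the endothelial markers. The text names the 12 genes with the largest rise and the 12 with the largest fall among those that passed with a mean of at least 1 CPM and both ATO libraries on one side of both controls; predicted genes and pseudogenes (18 higher and 15 lower among all genes that passed) are counted and not named. It also names up to 4 members with the smallest p of each list it describes, and a set of genes fixed beforehand for arsenic handling, oxidative stress, synapses, stress hormones and sex; the exceptions, chosen after their values were seen, are marked. Some genes that the rule takes are not reported here.

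The tests were tried on counts simulated for the 15713 genes from the means, library sizes and dispersions of these libraries, with 200 changed genes. Of the genes changed 1.5-fold, 2-fold and 4-fold, 53.7%, 88.1% and 98.5% were recovered, and 12 of 172 calls (6.98%) were false. The simulated genes varied independently of each other, with no shared shift of marker genes between samples. These rates thus need not hold for the real libraries. The alternatives were DESeq2 1.42.0 size factors in edgeR, library size only, no filter, a filter of at least 1 CPM in every library of 1 group, the replicate number as a block, limma-voom, the DESeq2 Wald test with independent filtering, leaving out each library in turn, and, for the lists, an estimated correlation, fry and a prior count of 0.5. A loess correction of each library for transcript length and GC content was added after the data had been seen. Where a library was left out, the remaining library of its group was assumed to vary like the other group. The replicate numbers come from the titles, and nothing says that they mark a shared litter or day, so they were not used in the fit. Figures were drawn with matplotlib 3.10.9.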

Results

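Messenger RNA from the hippocampus of C57BL/6 mice, an inbred laboratory strain, was measured by RNA sequencing in 4 libraries from animals 11 to 12 weeks old. The 2 libraries labelled control came from untreated mice. The other 2 came from mice labelled as exposed to ATO at 5000 ppb during development. The labels do not spell out ATO; the title of the series speaks of arsenic exposure and of offspring. The deposited table gave 15713 genes, and its counts summed to 14832214 and 15078919 in control replicates 1 and 2 and to 17251032 and 16696546 in ATO replicates 1 and 2. At these depths 1 count corresponds to between 0.0580 and 0.0674 CPM (counts scaled by library size). Mitochondrially encoded transcripts took 7.45% and 5.87% of the counts in the controls and 6.68% and 6.66% in ATO. Across genes, which are not independent replicates, the Pearson correlation of log2 CPM was 0.990 between the controls and 0.992 between the ATO libraries, against 0.981 to 0.982 between the groups. The Y-linked RNA helicase gene Ddx3y was counted in all 4 libraries, at 66.7 ± 0.808 CPM in control and 70.9 ± 2.97 in ATO (mean ± SD, n = 2), with a log2 fold change of 0.09 ± 0.08 (SE) and an adjusted p of 0.622; Xist was not analysed here.

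The design asks how the hippocampal transcriptome of mice exposed to ATO differs from that of control mice. Genes of the choroid plexus, the epithelium that secretes cerebrospinal fluid, had the largest rises in ATO: transthyretin (Ttr), a carrier of thyroid hormone, rose 62.7-fold (log2 5.97, against 5.39 without control replicate 1 and 6.98 without control replicate 2), and all 20 choroid plexus markers were higher. The endoplasmic reticulum chaperone gene Hspa5 and the glucocorticoid-induced gene Tsc22d3 rose by smaller amounts, 1.79-fold and 1.99-fold. Markers of CA1 pyramidal neurons were lower as a list, with a median log2 fold change of -0.36 over 12 markers (camera adjusted p = 0.00200, and adjusted p = 0.562 with an estimated correlation); the list call was lost without ATO replicate 1 (adjusted p = 0.114). Of 26 antioxidant genes and targets of the transcription factor NRF2, 0 passed in the main edgeR fit, limma-voom or DESeq2. In that edgeR fit 5 had an unadjusted p under 0.05, and with the replicate number as a block 2 passed. In all, 586 of the 15713 genes passed the threshold in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 451 higher and 135 lower in ATO, and 175 of them differed by more than 2-fold, 150 higher and 25 lower. For each of the 586 genes both ATO libraries lay on one side of both controls, as they did for 48.1% of all genes. Chance gives 33.3% as an average over the ways to split the libraries, and genes are not independent. A small p with 2 libraries per group favours such genes, so this is no separate support for the 586. The authors' deposited table marked 153 genes as differentially expressed, 135 higher and 18 lower, at an adjusted p under 0.05 and an absolute log2 fold change over 1; all 153 were among the 586. Without control replicate 2 the count was 222 (180 higher, 42 lower), without ATO replicate 1 300 genes were higher, and DESeq2's Wald test gave 316.

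**Figure D1:**
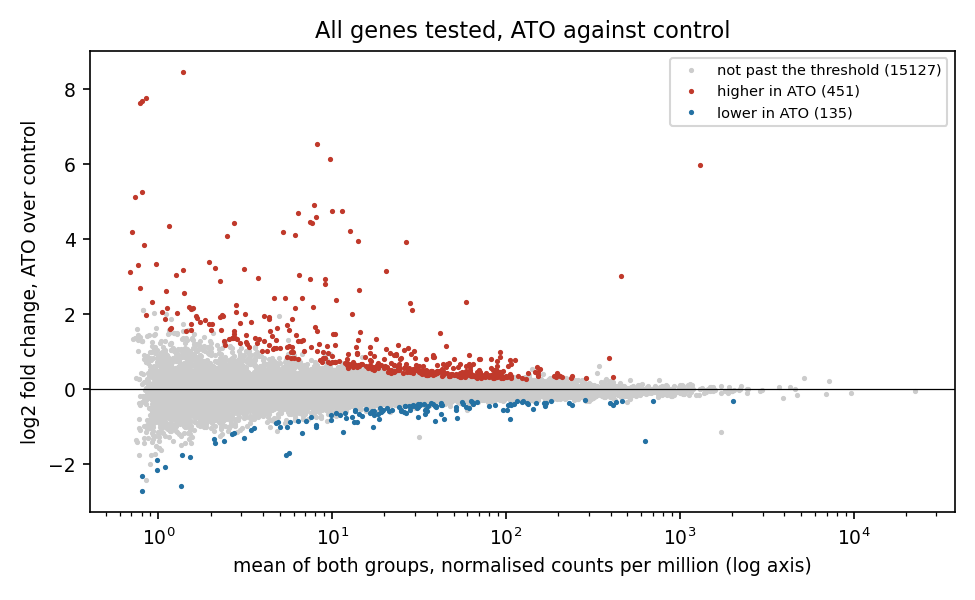
Log2 fold change of ATO over control (vertical axis) against the mean normalised CPM of both groups (horizontal log axis), 1 point per gene of the 15713 tested. The 451 genes higher in ATO reach further from 0 than the 135 lower ones; the values of genes with no count in either control are fitted and depend on the model.

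The 12 named genes with the largest rises were Wfdc2, Slc4a5, Tmem72, Ttr, Folr1, Cldn2, Mfrp, Otx2, Kcne2, Aqp1, Col8a1 and Cdh3, and 9 of them belong to the list of choroid plexus markers fixed before the data were examined. Ttr (ENSMUSG00000061808, chromosome 18 from 20665280 to 20674321, plus strand, GRCm38) went from 41.1 ± 29.2 normalised CPM in control to 2579.9 ± 415 in ATO (mean ± SD, n = 2 per group), a log2 fold change of 5.97 ± 0.33 (SE) with an adjusted p of 5.34e-08. Its counts were 301 and 933 in the controls and 39829 and 47729 in ATO. Slc4a5 (ENSMUSG00000068323, chromosome 6 from 83219828 to 83304945, plus strand), a sodium bicarbonate cotransporter, had 5 counts in both controls together against 552 in ATO, a ratio of 97.3 after division by depth with an exact binomial 95% interval from 41.4 to 301. Tmem72, which encodes a transmembrane protein, rose 70.0-fold from 0.266 ± 0.185 to 19.3 ± 3.27 CPM. The rises of Folr1 (a folate receptor), Cldn2 (a tight junction claudin), Mfrp (a membrane protein related to frizzled), Otx2 (a homeobox transcription factor), Kcne2 (a potassium channel subunit), Aqp1 (a water channel) and Col8a1 (a collagen chain) lay between log2 4.43 and 4.90, with adjusted p from 7.00e-08 to 2.84e-06. Wfdc2 (ENSMUSG00000017723, chromosome 2 from 164562413 to 164568510, plus strand), a secreted protein with whey acidic protein domains, had 0 counts in both controls and 44 and 50 in ATO, so it was at least 27.6-fold higher against a floor of 3 counts over the control group (adjusted p = 0.000117). Cdh3, which encodes P-cadherin, had 3 control counts against 75 in ATO, a ratio of 22.0 with a counting interval from 7.25 to 109. All 12 kept their call when each of the 4 libraries was left out in turn, but several sizes rested on 1 control. Without control replicate 1 the log2 fold change was 5.39 for Ttr, 7.78 for Slc4a5, 4.03 for Folr1 and 3.97 for Mfrp; Cdh3 then had no control count, so its fitted value is no bound. Without control replicate 2 it was 6.98 for Ttr, 5.86 for Slc4a5, 7.07 for Tmem72, 7.66 for Folr1, 6.69 for Mfrp, 5.46 for Otx2 and 3.39 for Cdh3.

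**Figure D2:**
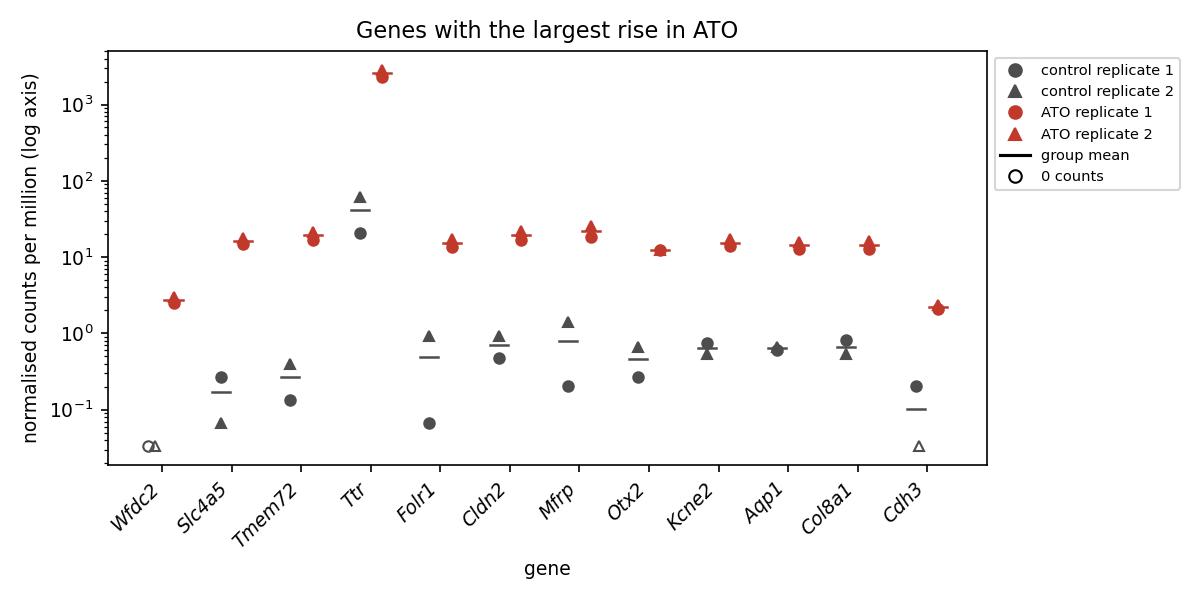
Normalised CPM (vertical log axis) of the 12 genes with the largest rises in ATO, with 1 point per library, horizontal lines at the group means and open symbols at the bottom for libraries with 0 counts. For all 12 genes both ATO libraries lie above both controls, and Ttr reaches a mean of 2579.9 CPM in ATO.

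All 20 choroid plexus markers rose in ATO, over all genes tested and adjusted over the list alone, with log2 fold changes from 2.33 to 6.53 and a median of 4.17. Beside Ttr, the most abundant of them was Enpp2, which encodes the lysophospholipase D autotaxin and rose 8.13-fold from 101 ± 20.04 to 819.7 ± 136 CPM (log2 3.02 ± 0.13, adjusted p = 1.25e-08). Kl, the gene of the anti-ageing protein klotho, rose 5.01-fold and the chloride channel gene Clic6 15.3-fold. The control hippocampus was not free of these transcripts: all 20 markers were counted in both controls, 9 of them at a mean of at least 1 CPM, and 1 of the 20 is also in another list. Relative to the control mean, the median marker stood at log2 4.01 in ATO replicate 1 and 4.20 in replicate 2. The list passed camera with a preset correlation (adjusted p = 1.97e-31); adjusted p = 0.552 with an estimated correlation. Of 14 markers of ependymal and other ciliated cells, which line the ventricles, 7 rose and 0 fell over all genes, 9 rose adjusted over the list alone, and the median log2 fold change was 1.06 (camera adjusted p = 1.57e-08, and adjusted p = 0.552 with an estimated correlation). Among them were the dynein light chain gene Dynlrb2 at 2.56, the adenylate kinase gene Ak7 at 1.77, Cfap126 at 1.74 and the radial spoke gene Rsph1 at 1.09. Among the ependymal markers 3 passed without control replicate 1, without control replicate 2, without ATO replicate 1 and in DESeq2's Wald test. Leaving out control replicate 1 gave an adjusted p of 0.114 for Cfap126. In the fit without control replicate 2 the adjusted p was 0.123 for Ak7 and 0.137 for Rsph1. The adjusted p without ATO replicate 1 was 0.0972 for Ak7 and 0.0899 for Rsph1. Calls also ended in DESeq2's Wald test for Rsph1 (adjusted p = 0.0589) and Cfap126 (0.0793). The log2 fold changes without control replicate 2 were 4.71 for Clic6 and 2.46 for Cfap126. Without control replicate 1 they were 3.45 and 1.26.

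Of 24 genes of heat shock proteins and the unfolded protein response 11 rose and 0 fell over all genes, and 14 rose adjusted over the list alone. The list had a median log2 fold change of 0.42 and passed camera (adjusted p = 3.86e-08), and adjusted p = 0.562 with an estimated correlation. Hspa5 (ENSMUSG00000026864, chromosome 2 from 34771970 to 34777547, plus strand), the main chaperone of the endoplasmic reticulum, rose 1.79-fold from 281 ± 12.8 to 503 ± 23.5 CPM (n = 2 per group, log2 0.84 ± 0.08, adjusted p = 1.18e-05). The protein disulfide isomerase Pdia4 rose by log2 0.92 ± 0.09, Sdf2l1 of the endoplasmic reticulum by 1.34 ± 0.13 and Xbp1, a transcription factor of the unfolded protein response, by 0.77 ± 0.08; these 4 calls held without each library in turn. In the same ATO libraries the choroid plexus markers had risen by a median of 4.17.

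Among 20 genes of the glucocorticoid list, 10 rose and 1 fell over all genes, and 11 rose and 1 fell adjusted over the list alone. The list, of which 4 members are also in another list, had a median of 0.42 and passed camera (adjusted p = 6.00e-05); adjusted p = 0.552 with an estimated correlation. Tsc22d3 (ENSMUSG00000031431, chromosome X from 140539528 to 140600659, minus strand), which encodes the leucine zipper protein GILZ, rose 1.99-fold from 61.9 ± 3.21 to 123 ± 3.30 CPM (n = 2 per group, log2 0.99 ± 0.08, adjusted p = 2.84e-06). The lipid droplet gene Plin4 rose by log2 1.55 ± 0.20, the cell cycle inhibitor gene Cdkn1a by 1.52 ± 0.18 and the kinase gene Sgk1 by 0.75 ± 0.09, and all 4 calls held without each library in turn. The gene that fell, Crhbp, encodes the binding protein of corticotropin-releasing hormone and was chosen after its values were seen: its log2 fold change was -0.62 ± 0.16 (adjusted p = 0.0435), and the call was lost without control replicate 2 (adjusted p = 0.291), without ATO replicate 1 (0.257), with library size only (0.0538) and in DESeq2's Wald test (0.0571). Among the glucocorticoid genes 7 passed without control replicate 2. The glucocorticoid receptor gene Nr3c1 did not pass, at -0.10 ± 0.09 (adjusted p = 0.601). The choroid plexus markers had risen by a median of 4.17 in the same libraries.

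As lists, markers of CA1 pyramidal neurons were lower in ATO and those of dentate granule neurons higher. The list medians were -0.36 for CA1 (camera adjusted p = 0.00200, and adjusted p = 0.562 with an estimated correlation) and 0.28 for the dentate gyrus (camera adjusted p = 0.00661, and adjusted p = 0.651 with an estimated correlation). Of 12 CA1 markers, 4 fell and 0 rose over all genes, and 7 fell adjusted over the list alone. Those past the threshold over all genes included Wfs1 (ENSMUSG00000039474, chromosome 5 from 36966104 to 36989205, minus strand), which encodes the endoplasmic reticulum protein wolframin and went from 99.1 ± 9.17 to 74.2 ± 13.01 CPM (log2 -0.42 ± 0.11, adjusted p = 0.0463), the decorin gene Dcn (-0.56 ± 0.10) and Pex5l (-0.37 ± 0.09), whose product regulates HCN channels. Of 19 dentate gyrus markers 2 rose, the cation channel gene Trpc6 by 0.66 ± 0.12 and the matrix protein gene Npnt by 0.43 ± 0.11, and 10 rose adjusted over the list alone. The ATO libraries stood apart from each other, with median CA1 markers at -0.49 and -0.13 relative to the control mean. Among the CA1 markers 0 passed without control replicate 2, 1 without control replicate 1 and 2 with library size only, without ATO replicate 1 and in DESeq2's Wald test. Among the dentate gyrus markers 1 passed with library size only, without control replicate 2, without ATO replicate 1 and in DESeq2's Wald test, 6 without control replicate 1 and 7 without ATO replicate 2. With control replicate 1 left out the adjusted p was 0.0522 for Wfs1 and 0.108 for Pex5l. When control replicate 2 was left out the adjusted p became 0.193 for the dentate gyrus list, 0.263 for Wfs1, 0.0649 for Dcn, 0.0710 for Pex5l and 0.261 for Npnt. A fit that omitted ATO replicate 1 gave an adjusted p of 0.114 for the CA1 list, 0.131 for the dentate gyrus list, 0.411 for Wfs1, 0.370 for Pex5l and 0.194 for Npnt. Other settings ended calls too, with library size only for Wfs1 (adjusted p = 0.0562) and Npnt (0.0511) and in DESeq2's Wald test for Wfs1 (0.0524) and Npnt (0.1296). Both ATO libraries also had the higher choroid plexus markers (median 4.17).

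**Figure D3:**
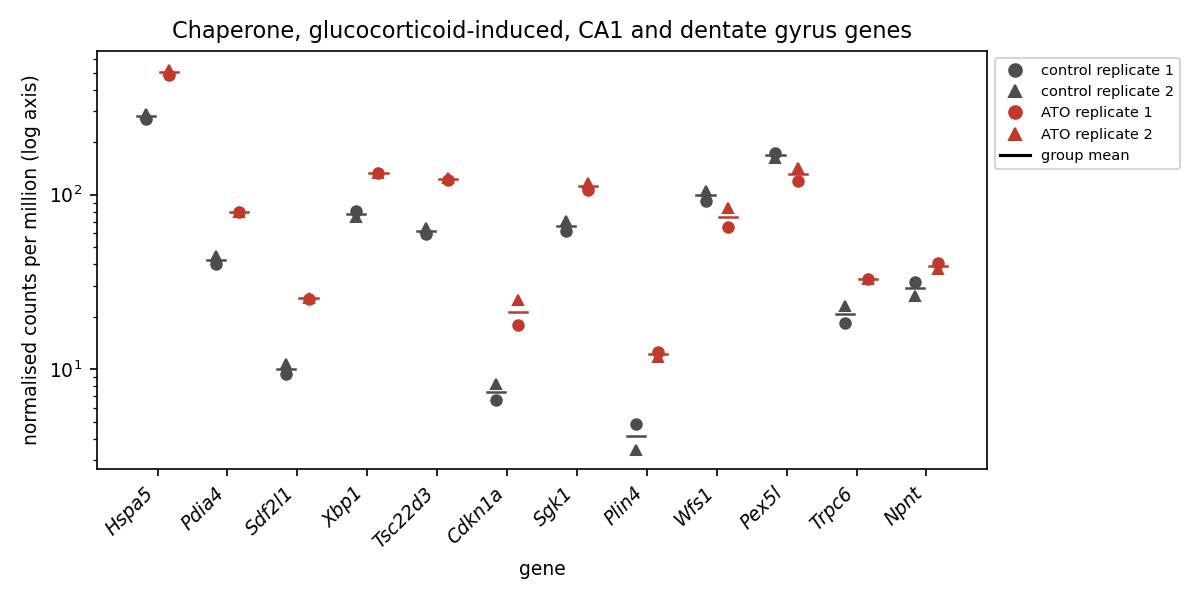
Normalised CPM (vertical log axis) of chaperone genes (Hspa5 to Xbp1), glucocorticoid-induced genes (Tsc22d3 to Plin4), CA1 markers (Wfs1 and Pex5l) and dentate gyrus markers (Trpc6 and Npnt), with 1 point per library and horizontal lines at the group means. Both ATO libraries lie outside both controls for each gene; for Wfs1 and Pex5l, ATO replicate 2 lies nearer to the controls than replicate 1.

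Interferon-stimulated and antigen-presentation genes were higher as a list. Of 23 tested, 2 rose and 0 fell, the class II histocompatibility gene H2-Aa by log2 1.94 ± 0.48 and the guanylate-binding protein gene Gbp2 by 1.34 ± 0.34; 8 rose adjusted over the list alone, and the median was 0.49 (camera adjusted p = 0.00182, and adjusted p = 0.562 with an estimated correlation). H2-Aa had 96 counts in ATO replicate 1 and 33 in replicate 2, and its log2 fold change without ATO replicate 1 was 1.02. Of 16 leptomeningeal and fibroblast markers 1 rose, the growth factor gene Igf2 (1.70 ± 0.30), and 1 fell, Dcn, which is also a CA1 marker. Igf2 was at 2.35 without control replicate 1 and at 1.25 without control replicate 2. Adjusted over the list alone 9 rose and 1 fell. The median was 0.69 (camera adjusted p = 0.00237, and adjusted p = 0.651 with an estimated correlation). The libraries of 1 group differed on these markers, with medians of 0.35 and -0.35 in the controls and 0.94 and 0.38 in ATO. Among the interferon genes 0 passed without ATO replicate 1, 1 without control replicate 2, in limma-voom and in DESeq2's Wald test, 4 after the length and GC correction and 8 without ATO replicate 2. Among the meningeal markers 0 passed without control replicate 2, 4 after the length and GC correction, 6 without control replicate 1 and 11 without ATO replicate 2. Omitting control replicate 1 gave an adjusted p of 0.0760 for H2-Aa. Leaving out control replicate 2 gave an adjusted p of 0.146 for the meningeal list, 0.265 for H2-Aa, 0.243 for Gbp2, 0.0699 for Igf2 and 0.0649 for Dcn. In the fit without ATO replicate 1 the adjusted p was 0.114 for the meningeal list, 0.459 for H2-Aa and 0.109 for Gbp2. Besides, calls were lost in limma-voom for H2-Aa (adjusted p = 0.0820) and in DESeq2's Wald test for Gbp2 (0.148). In the same ATO libraries the choroid plexus markers had risen by a median of 4.17.

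Of 19 genes of thyroid hormone and retinoid signalling 5 rose and 0 fell, and 6 rose and 1 fell adjusted over the list alone. Those that rose over all genes included Ttr, which is also a choroid plexus marker, the deiodinase gene Dio2 (0.86 ± 0.12), the transcription factor gene Klf9 (0.35 ± 0.08) and, chosen after its values were seen, the thyroxine transporter gene Slco1c1 (0.31 ± 0.08). The median was 0.14 (camera adjusted p = 0.0347, and adjusted p = 0.562 with an estimated correlation). The mean was 0.49, with Ttr highest at 5.97, and the list was not tested without Ttr. Of 18 growth factor and receptor genes 2 rose and 0 fell. Igfbp2, which encodes a binding protein of insulin-like growth factors, rose by 1.496 ± 0.11 (adjusted p = 6.46e-07). Igf2 rose by 1.70 (2.35 without control replicate 1 and 1.25 without control replicate 2). In this list 3 rose adjusted over the list alone, and the median was 0.16 (camera adjusted p = 0.0412, and adjusted p = 0.562 with an estimated correlation). The neurotrophin gene Bdnf did not pass, at -0.21 ± 0.08 (adjusted p = 0.197). Of 20 clock genes 2 rose, Per2 by 0.69 ± 0.09 and Nfil3 by 0.66 ± 0.17, and 5 rose adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.0446, and adjusted p = 0.562 with an estimated correlation). Among the thyroid and retinoid genes 2 passed without control replicate 2 and 3 without ATO replicate 1. Among the growth factor genes 1 passed without control replicate 2. Among the clock genes 1 passed with library size only, without control replicate 1 and in DESeq2's Wald test. The adjusted p without control replicate 1 was 0.0844 for Slco1c1 and 0.185 for Nfil3. With control replicate 2 left out the adjusted p was 0.123 for the growth factor list, 0.107 for the clock list, 0.117 for Klf9, 0.145 for Slco1c1 and 0.0699 for Igf2. When ATO replicate 1 was left out the adjusted p became 0.108 for the growth factor list, 0.149 for the clock list, 0.0807 for Klf9, 0.142 for Slco1c1 and 0.116 for Nfil3. A fit that omitted ATO replicate 2 gave an adjusted p of 0.105 for the thyroid list, 0.0637 for the growth factor list, 0.0844 for the clock list and 0.233 for Slco1c1. Calls also ended with library size only for Nfil3 (adjusted p = 0.0581), in limma-voom for Slco1c1 (0.0541) and in DESeq2's Wald test for Slco1c1 (0.138) and Nfil3 (0.114). The clock list also missed the threshold after a correction for gene length and GC content (adjusted p = 0.0656) and with the replicate number as a block (0.0631). Both ATO libraries also had the higher choroid plexus markers (median 4.17).

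**Figure D4:**
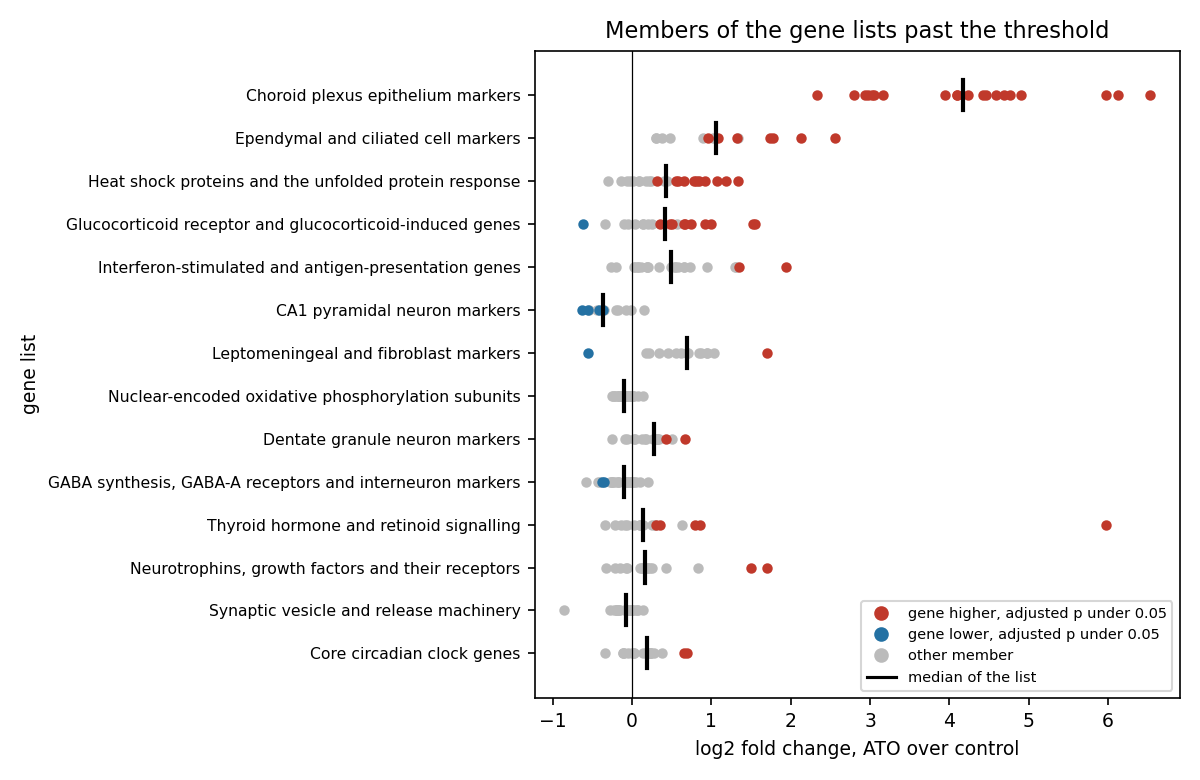
Log2 fold change of ATO over control (horizontal axis) of each tested member of the 14 lists that passed camera with a preset correlation (rows), with black bars at the list medians and colour for genes past the threshold. The choroid plexus markers have the highest median of the 14, 4.17, and the medians of the 4 lower lists lie between -0.36 and -0.07.

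Of 28 genes of GABA synthesis, GABA-A receptors and interneurons 2 fell and 0 rose, the neuropeptide Y gene Npy by log2 -0.38 ± 0.09 and the receptor subunit gene Gabra3 by -0.36 ± 0.09; 3 fell adjusted over the list alone, and the median was -0.10 (camera adjusted p = 0.00942, and adjusted p = 0.562 with an estimated correlation). Of 27 genes of synaptic vesicles and release 0 passed in edgeR, limma-voom or DESeq2, 7 had an unadjusted p under 0.05, all 7 lower, and 2 were lower adjusted over the list alone; the vesicular glutamate transporter gene Slc17a6 was at -0.85 ± 0.23 (adjusted p = 0.0575) and the calcium channel gene Cacna1b at -0.28 ± 0.08 (0.0619). That list's median was -0.07 (camera adjusted p = 0.0446, and adjusted p = 0.562 with an estimated correlation). Of 42 nuclear genes of oxidative phosphorylation 0 passed in any of the 3 tools, over all genes or (edgeR) adjusted over the list alone, and 4 had an unadjusted p under 0.05; Ndufb9 of complex I was at -0.24 ± 0.08 and the cytochrome c oxidase subunit gene Cox7a2 at -0.25 ± 0.08. Its median was -0.10 (camera adjusted p = 0.00586, and adjusted p = 0.562 with an estimated correlation), and the call ended after the length and GC correction (adjusted p = 0.522). Among the interneuron genes 0 passed with library size only, without control replicate 2, without ATO replicate 1 and in DESeq2's Wald test and 1 after the length and GC correction, without control replicate 1 and in limma-voom. Among the vesicle genes 1 passed without control replicate 1, without ATO replicate 1 and without ATO replicate 2 and 2 after the length and GC correction. Omitting control replicate 1 gave an adjusted p of 0.0742 for the vesicle list, 0.135 for Npy and 0.0618 for Gabra3. Leaving out control replicate 2 gave an adjusted p of 0.0513 for the vesicle list, 0.107 for the respiratory chain list, 0.0611 for Npy and 0.219 for Gabra3. In the fit without ATO replicate 1 the adjusted p was 0.108 for the interneuron list, 0.176 for the vesicle list, 0.0980 for the respiratory chain list, 0.135 for Npy and 0.429 for Gabra3. The adjusted p without ATO replicate 2 was 0.0813 for the vesicle list and 0.110 for Npy. Other settings ended calls too, with library size only for Npy (adjusted p = 0.05002) and Gabra3 (0.0575), after the length and GC correction for Npy (0.0996), in limma-voom for Gabra3 (0.0515) and in DESeq2's Wald test for Npy (0.116) and Gabra3 (0.0997). Slc17a6 passed without control replicate 1 (-1.21, adjusted p = 0.00824), without ATO replicate 1 (0.0393), without ATO replicate 2 (0.00972) and after the length and GC correction (0.0429), but was at -0.38 (0.465) without control replicate 2. Cacna1b passed after the correction (0.0413). With the replicate number as a block in edgeR, Slc17a6 (adjusted p = 0.00599), Cacna1b (0.0127), Ndufb9 (0.0252) and Cox7a2 (0.0269) passed, all lower. The block gave 5 interneuron, 2 vesicle and 3 respiratory chain genes. The choroid plexus markers had risen by a median of 4.17 in the same libraries.

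Among 30 glutamate receptor and postsynaptic scaffold genes 1 fell, the AMPA receptor subunit gene Gria4 (log2 -0.33 ± 0.09, adjusted p = 0.0444); 1 rose and 3 fell adjusted over the list alone, and the list did not pass (median -0.08, camera adjusted p = 0.0545). With control replicate 1 left out the adjusted p was 0.0601 for Gria4. When control replicate 2 was left out the adjusted p became 0.175 for Gria4. A fit that omitted ATO replicate 1 gave an adjusted p of 0.245 for Gria4. Omitting ATO replicate 2 gave an adjusted p of 0.105 for Gria4. Besides, calls were lost with library size only for Gria4 (adjusted p = 0.0538) and in DESeq2's Wald test for Gria4 (0.122). Among the glutamate receptor genes 0 passed with library size only, without control replicate 1, without control replicate 2, without ATO replicate 1 and in DESeq2's Wald test and 2 after the length and GC correction. The NMDA receptor subunit genes Grin1, Grin2a and Grin2b were at -0.12 ± 0.09, -0.15 ± 0.10 and -0.26 ± 0.07 and the AMPA subunit gene Gria1 at -0.12 ± 0.07, with adjusted p from 0.0738 to 0.514. With the replicate number as a block in edgeR, 4 glutamate receptor genes passed, Grin2b among them (adjusted p = 0.0124). The DNA methyltransferase gene Dnmt3a was at -0.14 ± 0.11 (adjusted p = 0.560). Choroid plexus markers had risen by a median of 4.17 in the same ATO libraries.

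Few of the genes tied to arsenic and oxidative stress passed, but of all genes tested only 3.73% did. Whether the share in these lists differs from that was not tested. Of 26 NRF2 targets and partners 0 passed in edgeR, limma-voom or DESeq2, over all genes or (edgeR) adjusted over the list alone, and 5 had an unadjusted p under 0.05, 4 higher and 1 lower. The NRF2 gene Nfe2l2 was at log2 0.44 ± 0.13 (adjusted p = 0.0928), the quinone reductase gene Nqo1 at 0.69 ± 0.26 (0.173) and the heme oxygenase gene Hmox1 at 0.43 ± 0.22 (0.336). With the replicate number as a block in edgeR, 2 of the 26 passed, Nfe2l2 among them (adjusted p = 0.0383). The list median was -0.01 and the mean 0.06, which differ in sign; the median changed sign between the scalings tried (-0.0109 to 0.0226), and the list did not pass (camera direction up, adjusted p = 0.638). Of 15 genes of arsenic methylation, methyl group supply and transport 2 rose, over all genes and adjusted over the list alone: the glucose transporter gene Slc2a1 by 0.68 ± 0.08 (adjusted p = 0.000241) and Mat2a, which makes S-adenosylmethionine, by 0.35 ± 0.08 (0.0317). The arsenic methyltransferase gene As3mt was at -0.18 ± 0.19 (0.680) and Gsto1, which encodes a glutathione transferase that reduces arsenic species, at -0.01 ± 0.10 (0.960). Of 11 metallothionein and metal-responsive genes 1 fell, over all genes and adjusted over the list alone, the transferrin receptor gene Tfrc (-0.40 ± 0.08), and the metallothionein genes Mt1 and Mt2 were at 0.00 ± 0.10 and 0.25 ± 0.09 (0.991 and 0.164). The arsenic list (median 0.00, camera adjusted p = 0.638) and the metal list (median 0.16, 0.490) did not pass. Choroid plexus markers had risen by a median of 4.17 in the same ATO libraries, and whether such tissue contributed to the rise of Slc2a1 or Mat2a was not tested. Among the NRF2 genes 1 passed without control replicate 1 and without ATO replicate 2. Among the arsenic genes 1 passed without control replicate 1, without ATO replicate 1 and without ATO replicate 2. Among the metal genes 0 passed without ATO replicate 2 and 2 after the length and GC correction and without control replicate 1. Mt2 passed after the length and GC correction (adjusted p = 0.0413) and with the replicate number as a block (0.0419), where 4 metal genes passed. It was at 0.39 without control replicate 1 and at 0.12 without control replicate 2. Leaving out control replicate 1 gave an adjusted p of 0.109 for Mat2a. In the fit without ATO replicate 1 the adjusted p was 0.0757 for Mat2a. The adjusted p without ATO replicate 2 was 0.0615 for Mat2a and 0.0662 for Tfrc. 

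The 12 genes with the largest falls under the rule for named genes reached smaller changes than the 12 that rose. Pla2g4e (ENSMUSG00000050211, chromosome 2 from 120166412 to 120245335, minus strand), a cytosolic phospholipase A2, fell 3.37-fold from 8.41 ± 0.473 to 2.48 ± 0.789 CPM (n = 2 per group, log2 -1.75 ± 0.25, adjusted p = 0.000895), and Col6a4, a collagen VI chain, fell 3.24-fold from 8.67 ± 0.658 to 2.67 ± 0.534 CPM (log2 -1.70 ± 0.23, adjusted p = 0.000643). The calpain gene Capn11 fell 5.97-fold, from counts of 53 and 16 to 6 and 7 (log2 -2.58, against -1.45 without control replicate 1 and -3.21 without control replicate 2). The vomeronasal receptor gene Vmn2r1 was at log2 -2.09 ± 0.49 (-2.91 without ATO replicate 2 and -1.55 without ATO replicate 1). Oacyl was at -1.81 ± 0.44, the hedgehog-responsive transcription factor gene Gli1 at -1.44 ± 0.35 and the transcription factor gene Creb5 at -1.29 ± 0.33. The Wnt ligand gene Wnt9a was at -1.17 ± 0.24, the relaxin receptor gene Rxfp1 at -1.15 ± 0.23 and the kelch domain gene Klhdc9 at -1.09 ± 0.28. Lars2, the mitochondrial leucyl-tRNA synthetase gene, was at -1.38 ± 0.35, from counts of 12460 and 14711 in control and 9543 and 2489 in ATO (-2.60 without ATO replicate 1 and -0.73 without ATO replicate 2); it is reported as uncertain because part of it resembles ribosomal RNA. Pla2g4e and Col6a4 kept their calls without each library in turn and the other 9 described here did not. With control replicate 1 left out the adjusted p was 0.231 for Capn11, 0.0800 for Vmn2r1, 0.192 for Oacyl, 0.111 for Lars2, 0.263 for Creb5, 0.105 for Wnt9a and 0.0819 for Klhdc9. When control replicate 2 was left out the adjusted p became 0.153 for Vmn2r1, 0.262 for Gli1, 0.232 for Lars2, 0.166 for Rxfp1 and 0.194 for Klhdc9. A fit that omitted ATO replicate 1 gave an adjusted p of 0.214 for Vmn2r1, 0.0696 for Gli1, 0.0932 for Creb5 and 0.287 for Klhdc9. Omitting ATO replicate 2 gave an adjusted p of 0.0668 for Oacyl and 0.0836 for Gli1. Calls also ended with library size only for Lars2 (adjusted p = 0.0631), Creb5 (0.0552) and Klhdc9 (0.0511), in limma-voom for Capn11 (0.0663), Oacyl (0.0519), Gli1 (0.0515) and Creb5 (0.0681) and in DESeq2's Wald test for Vmn2r1 (0.138), Oacyl (0.118), Gli1 (0.143), Lars2 (0.611), Creb5 (0.118) and Klhdc9 (0.156). In the same ATO libraries the choroid plexus markers had risen by a median of 4.17.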

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

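The length and GC correction was added after the data had been seen; all other settings were fixed beforehand. The 586 genes past the threshold (451 higher, 135 lower) stayed within 1.5 times under DESeq2 size factors, library size only, either filter setting, limma-voom and the length and GC correction (508 to 704). They became 316 (252 higher, 64 lower) with the DESeq2 Wald test, 312 of them shared, and 222 to 611 with 1 library left out (180 to 443 higher, 42 to 168 lower), the fewest without control replicate 2; without ATO replicate 1 300 were higher. The cause was not tested for the Wald test. Leaving out a library leaves fewer samples, but that alone does not account for counts that moved in both directions. With the replicate number as a block the count was 1366 (890 higher, 476 lower), and all 586 were among them. The block gave 10 dentate gyrus, 7 CA1, 8 interferon and 10 meningeal genes, against 2, 4, 2 and 2 in the main fit. Same-numbered libraries deviated with a correlation of 0.0877 across genes. Replicate 2 minus replicate 1 correlated with transcript length at -0.127 in the controls and -0.0981 in ATO, and with GC content at 0.131 and 0.0856. Nothing says what the numbers mark, so whether same-numbered libraries share a litter, day or batch stays open. The 14 lists became 7 (without ATO replicate 1) to 17 with 1 library left out, 13 with the block, 12 after the length and GC correction, and 0 with an estimated correlation or with fry. The mean correlation within groups was 0.991 (Pearson) and 0.994 (Spearman). Of 88 named genes that passed, 43 kept their call without each library in turn. Direction turned only for genes that had not passed: Gsto1 with the length and GC correction (0.0329), Mt1 with DESeq2 size factors (-0.000337) and the Wald test (-0.000503), and, with 1 library left out, Grin2a (-0.289 to 0.00420), Dnmt3a (-0.306 to 0.0164), Nr3c1 (-0.223 to 0.0208), Gsto1 (-0.0841 to 0.0557), Mt1 (-0.150 to 0.173) and Atf4 (-0.0151 to 0.0505), all log2 fold changes. At 1.5-fold the simulation recovered 53.7% of changed genes.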

Other observations

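Beyond the lists described with the comparison, several neuronal and glial groups held single genes that passed in edgeR, and none of these lists passed camera with all 4 libraries. Both ATO libraries also had the higher choroid plexus (median 4.17) and ependymal markers (median 1.06). Whether such tissue contributed to the genes named here was not tested. Among 30 monoamine and acetylcholine genes the serotonin receptor genes Htr2c (log2 0.68 ± 0.09, adjusted p = 0.000514) and Htr1a (0.40) rose and the monoamine oxidase gene Maoa (-0.41) fell, with 2 higher and 2 lower adjusted over the list alone. Among 26 neurogenesis genes Bhlhe22 (0.53), the cyclin gene Ccnd2 (0.50) and Sox11 (0.50) rose and the stem cell factor gene Sox2 (-0.40) fell (6 and 1 adjusted over the list alone). Of 25 immediate early genes the scaffold gene Homer1 (0.60) rose (5 higher and 2 lower adjusted over the list alone), and of 18 CA3 and CA2 markers Coch (1.203), which alone passed adjusted over the list alone too. Of 16 inflammation genes the adhesion molecule gene Vcam1 (0.82) and the lipocalin gene Lcn2 (2.63, with 4.70 without control replicate 1 and 1.80 without control replicate 2) rose, the same number as adjusted over the list alone, and of 26 chromatin enzymes Hdac4 (0.58), with 4 higher adjusted over the list alone. Of 26 Wnt and Notch genes Hey2 (1.57) and Sfrp1 (1.11) rose (4 higher and 1 lower adjusted over the list alone), and of 22 apoptosis genes Cdkn1a and Apaf1 (0.48) did (3 adjusted over the list alone). Htr2c, Bhlhe22, Ccnd2, Homer1, Coch, Vcam1, Hdac4, Hey2 and Cdkn1a kept their calls without each library in turn. The others did not. The camera adjusted p was 0.792 for the monoamine, 0.0818 for the neurogenesis, 0.308 for the immediate early and 0.195 for the CA3 and CA2 list. It was 0.0901 for inflammation, 0.579 for chromatin, 0.316 for Wnt and Notch and 0.0818 for apoptosis. With the replicate number as a block 5 monoamine, 9 neurogenesis, 6 immediate early and 2 CA3 and CA2 genes passed. The block also gave 2 inflammation, 5 chromatin, 5 Wnt and Notch and 3 apoptosis genes. Leaving out control replicate 1 gave an adjusted p of 0.1005 for Maoa, 0.0788 for Sox11, 0.132 for Sox2 and 0.176 for Sfrp1. In the fit without control replicate 2 the adjusted p was 0.265 for Htr1a, 0.116 for Maoa, 0.0691 for Sox11, 0.0730 for Sox2, 0.148 for Lcn2 and 0.235 for Apaf1. The adjusted p without ATO replicate 1 was 0.0788 for Maoa, 0.0505 for Sox11, 0.0583 for Sox2 and 0.129 for Apaf1. With ATO replicate 2 left out the adjusted p was 0.220 for Htr1a, 0.191 for Maoa, 0.0757 for Sox11, 0.184 for Sox2 and 0.101 for Sfrp1. Other settings ended calls too, with library size only for Htr1a (adjusted p = 0.0514), Maoa (0.0511), Sox2 (0.0514) and Sfrp1 (0.0545), in limma-voom for Htr1a (0.0518) and in DESeq2's Wald test for Htr1a (0.138), Maoa (0.132), Sox11 (0.0793), Sox2 (0.115), Lcn2 (0.0592), Sfrp1 (0.110) and Apaf1 (0.111). With 1 library left out 3 of these lists passed, all up, inflammation (adjusted p = 0.0157) and apoptosis (0.0377) without control replicate 1 and the immediate early genes (0.0144) without control replicate 2. Over all settings except the replicate block, left-out libraries included, 1 to 4 of the monoamine, 2 to 6 of the neurogenesis, 1 to 3 of the immediate early, 1 to 2 of the CA3 and CA2, 1 to 2 of the inflammation, 1 to 3 of the chromatin, 1 to 3 of the Wnt and Notch and 1 to 3 of the apoptosis genes passed.

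The glial and vascular markers that passed went in both directions. Choroid plexus markers had risen by a median of 4.17 in the same ATO libraries, and whether such tissue contributed to the changes below was not tested. Of 18 astrocyte markers the connexin gene Gjb6 (0.44) and the amino acid transporter gene Slc7a10 (0.46) rose (6 higher and 2 lower adjusted over the list alone), of 20 oligodendrocyte markers Opalin (-0.66) fell (1 adjusted over the list alone), and of 15 precursor markers Gpr17 (0.43) rose and Cspg4 (-0.51) fell (1 and 1 adjusted over the list alone). Of 22 endothelial and mural markers the VEGF receptor gene Kdr (-0.63) fell (3 adjusted over the list alone). Of the 20 microglia, 8 blood, 13 mitochondrially encoded and 8 sex-linked genes 0 passed in edgeR, limma-voom or DESeq2, or (edgeR) adjusted over the list alone. At an unadjusted p under 0.05 there were 1, 0, 0 and 2. Among neighbouring regions, Sulf1 rose (2.64) and Tshz2 fell (-0.59) of 18 neocortex markers, Zic1 rose (0.85) of 17 thalamus markers, Ppp1r1b rose (0.46) of 16 striatal markers and Gpr101 fell (-0.88) of 13 subiculum markers. Adjusted over the list alone these regions had 1 higher and 3 lower, 2 and 1, 1 and 0, and 1 and 4. The neocortex list had a median of -0.12, against 2.64 for Sulf1. Of these named genes Sulf1 kept its call without each library in turn. When control replicate 1 was left out the adjusted p became 0.0733 for Slc7a10, 0.164 for Cspg4, 0.138 for Kdr and 0.0722 for Ppp1r1b. A fit that omitted control replicate 2 gave an adjusted p of 0.116 for Gjb6, 0.0941 for Slc7a10, 0.0638 for Opalin, 0.0893 for Gpr17, 0.112 for Cspg4, 0.200 for Tshz2, 0.172 for Zic1 and 0.0872 for Gpr101. Omitting ATO replicate 1 gave an adjusted p of 0.110 for Gjb6, 0.0640 for Opalin and 0.165 for Zic1. Leaving out ATO replicate 2 gave an adjusted p of 0.144 for Slc7a10, 0.280 for Cspg4, 0.0560 for Kdr and 0.0639 for Ppp1r1b. Besides, calls were lost with library size only for Cspg4 (adjusted p = 0.0633), in limma-voom for Cspg4 (0.0518) and in DESeq2's Wald test for Slc7a10 (0.0680), Cspg4 (0.153) and Kdr (0.0655). Over all settings except the replicate block, left-out libraries included, 0 to 4 astrocyte, 0 to 1 oligodendrocyte, 0 to 2 precursor, 0 to 3 vessel, 0 microglia, 0 to 1 blood, 0 to 2 mitochondrially encoded, 0 sex-linked, 1 to 3 neocortex, 0 to 3 thalamus, 1 striatal and 0 to 3 subiculum genes passed. The camera adjusted p of these lists was 0.476 for astrocytes, 0.195 for oligodendrocytes, 0.573 for their precursors, 0.638 for vessels, 0.765 for microglia, 0.579 for blood, 0.765 for mitochondrially encoded and 0.765 for sex-linked genes. For the neighbouring regions it was 0.195 (neocortex), 0.344 (thalamus), 0.614 (striatum) and 0.0818 (subiculum). With the replicate number as a block 7 astrocyte, 2 oligodendrocyte, 2 precursor and 3 vessel genes passed. The block also gave 4 neocortex, 3 thalamus, 1 striatal and 5 subiculum genes, and 0 microglia, blood, mitochondrially encoded or sex-linked genes. The mitochondrially encoded list, whose medians were 0.21 and -0.21 in the controls and -0.06 and 0.02 in ATO, passed in opposite directions, up without control replicate 1 (adjusted p = 0.0157) and down without control replicate 2 (0.00206). The subiculum list passed down without control replicate 1 (0.00836), the vessel list down without control replicate 2 (0.00786) and the blood list down without ATO replicate 1 (0.0306). Within the unfolded protein response, Atf4 (0.02 ± 0.08, adjusted p = 0.931) and its target Ddit3 (0.17 ± 0.11, 0.475), chosen after their values were seen, did not pass.

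All tests of explanations below were chosen after the results had been seen, except the count of other splits of the libraries. The 20 choroid plexus markers rose in both ATO libraries, among them the abundant Ttr (2579.9 ± 415 CPM) and Enpp2 (819.7 ± 136 CPM). Scaling moves every gene alike, and with library size only the median log2 fold change of all genes was 0.00175 against 4.17 for the markers, so scaling does not account for the rise. More choroid plexus tissue in the ATO samples, for example from dissection, and an effect of ATO on the choroid plexus both stay open and cannot be told apart: the count of 20 does not decide between them, no library separates exposure from dissection, and with 2 libraries against 2 the smallest two-sided exact permutation p is 0.333.

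Of the 24 chaperone and unfolded protein response genes 11 rose, and of the 20 glucocorticoid genes 10 rose and 1 fell, in the same libraries. A trend with gene length or GC content as the whole cause is argued against, since both lists passed camera after the correction (adjusted p = 1.45e-08 and 4.21e-05; over all alternatives the range was 8.07e-10 to 0.562 and 3.37e-05 to 0.552). If choroid plexus tissue had carried them, their excess over the control mean may be expected to follow that of the choroid plexus markers, which was 1.25 (1.19 to 1.29) times as large in ATO replicate 2 as in replicate 1 (median, 95% bootstrap interval over genes). The ratio was 0.925 (0.834 to 1.01) for the 11 chaperone genes that rose and 1.03 (0.845 to 1.40) for the 10 glucocorticoid genes, and the 7 ependymal markers that rose, another tissue of the ventricle, had 0.775 (0.400 to 0.888). As ventricular tissue thus had no single ratio and this rests on a single pair of ATO libraries, choroid plexus tissue, an effect of ATO and handling of the animals cannot be told apart for these genes.

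As lists, CA1 markers were lower and dentate gyrus markers higher in ATO (4 of 12 fell and 2 of 19 rose). The length and GC correction left both lists past the threshold (adjusted p = 0.00146 and 0.0128; over all alternatives 1.02e-06 to 0.562 and 0.000337 to 0.651), which argues against such a trend as the whole cause. Between the ATO libraries, which had the same exposure, the lists moved apart too: CA1 markers were lower in replicate 1 than in replicate 2 with a median log2 difference of -0.36, in 9 of 12 markers, and dentate gyrus markers higher by 0.13, in 18 of 19, at percentiles 0 and 100 of 10000 random lists of like expression. Between the controls, replicate 1 minus replicate 2, dentate gyrus markers differed by 0.23 (percentile 100), subiculum markers by -0.29, 9 of 13 lower (percentile 0), and CA1 markers by -0.00111 (percentile 51.6), so markers of subfields moved apart there too, but not those of CA1. Different shares of the subfields in the dissected samples and an effect of ATO on CA1 cannot be told apart, since libraries of 1 group differed in subfield markers in both groups, CA1 markers differed in the ATO pair only, and each group has only 1 pair.

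The 4 libraries can be split into 2 and 2 in 3 ways. Of the 3, the real one gave 586 genes and the highest of the others 0 in edgeR (at most 370 genes at an unadjusted p under 0.05). The other splits put an ATO library with a control in each group, so differences between ATO and control widen the spread within groups. Few calls were thus to be expected there, and 3 splits are too few for a share under 0.05. The 1292 long noncoding genes had a median log2 fold change of -0.13, with 64.2% below 0, against 0.00 for 13870 protein-coding genes, and a median of -0.10 after the length and GC correction; replicate 2 minus replicate 1 gave -0.11 in the controls and -0.01 in ATO. Gm23935, an annotated microRNA gene chosen after its values were seen, had 34663 and 35705 counts in the controls, 29940 in ATO replicate 1 and 7181 in replicate 2, the library in which Lars2 was also lowest. Gm23935 did not pass in the main test (log2 -1.13, adjusted p = 0.111). It passed in limma-voom (0.0452) and with the replicate number as a block (0.000219). Its log2 fold change was -2.45 without ATO replicate 1 and -0.46 without ATO replicate 2. Whether these reads come from a microRNA was not tested. The cation channel gene Trpm3 (0.79 ± 0.09), the carbonic anhydrase gene Car12 (0.67 ± 0.08) and the angiotensin-converting enzyme gene Ace (2.31 ± 0.15) rose. They were also chosen after their values were seen and are in none of the lists. With 1 library left out they ranged from 0.65 to 0.93 (Trpm3), 0.63 to 0.71 (Car12) and 2.09 to 2.56 (Ace). Whether choroid plexus tissue, whose markers had risen by a median of 4.17 in the same ATO libraries, contributed to these rises was not tested.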
